A study of Mus musculus with 2 samples.

How the data were processed

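RNA from femoral bone marrow of 8-day-old mice was extracted with Trizol, amplified to biotin-labelled cRNA and hybridised to Illumina MouseWG-6 v2.0 bead arrays, per the labels' protocols. The groups were taken from the genotype labels, 1 array for wild type and 1 for Dnmt2-/-. Each array reports 45281 probes.

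The deposited non-normalized table gives 1 signal intensity per probe and array on a linear scale. The intensities ran from 74.1 to 25571 on the array labelled wild type and from 75.6 to 22805 on the array labelled Dnmt2-/-, and background had not been subtracted. The scanner and image software are not given in the sources used here. The deposited table also gives a detection p-value per probe and array, low for probes above background. A second deposited table holds intensities that the authors normalized by a method not given in the sources used here. These values were on a linear scale, not centred, with medians of 101.8 and 101.1, and their direction followed the same array's signal, with a rank correlation above 0.999. It left 1071 probes blank on both arrays. It was used only as an alternative. Its log2 ratios had a Pearson correlation of 0.949 with those used here across 16728 probes detected on both arrays.

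Probes were named from the platform annotation supplied with the tables. Of all probes, 34885 had 1 gene symbol, 18 had several and were not used for genes, and 10378 were not named here. The Entrez identifiers of 34807 named probes were found in the mouse reference (GRCm38.p6), and no symbol needed updating. The tables name no genome build, so the reference served only for names, chromosomes and the order of neighbouring genes, and no coordinates are printed. The named probes covered 19057 genes, 9172 of them with over 1 probe.

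Background was corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the background mean and SD inferred from the detection p-values because no control probes were given. The fitted background was 90.9 (SD 3.16) on the array labelled wild type and 94.9 (SD 3.43) on the array labelled Dnmt2-/-. An offset of 16 was added, and values were taken to log2 and quantile normalized. Ratios are differences of these log2 values. The offset and the low signal over background shrink folds, most for dim genes. For each gene the probe with the highest mean was used, and a gene counted as detected at a detection p-value below 0.01. By this rule 9746 genes were detected on both arrays and 7619 on neither. For 83 genes the chosen probe was detected on 1 array and another probe on the other. Where a gene was detected on 1 array only, the difference is given as at least N-fold, with the dimmer value set to the higher of its own and the lowest normalized value among detected probes of that array. Where its own value was the higher, the bound equals the measured ratio.

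With 1 array per group no test was run and no p-value was computed for any difference. Before the data were examined, 38 gene lists, the thresholds, the alternatives and the rule for named genes were fixed. The rule names Dnmt2, the 10 highest and 10 lowest ratios among genes detected on both arrays and the 3 largest bounds in each direction. It also names up to 4 members in the direction of the median, and up to 2 against it by over 1.5-fold, in each list that stood apart or marks a haematopoietic lineage, and all detected sex-specific genes and listed neighbours of Dnmt2. Other genes in the text were chosen after their values were seen, namely Bglap, Bglap2, S100a8, S100a9, Mpo, Elane, Hba-a1, Hbb-bs, Ear6, Ear10, Epx and Prg2 in the report and those of the closing section. Lists with under 5 detected genes have no median. The percentile of a median comes from 10000 random lists of the same size, drawn within 20 bins of mean expression. It describes these 2 arrays, since genes are not replicates.

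The steps were tested on simulated arrays with 200 changed genes and an SD of 0.2 between arrays on the log2 scale. On both simulated arrays 10271 genes were detected. Genes simulated at a log2 ratio of 1, -1, 2 and -2 were estimated at medians of 0.89, -0.81, 1.76 and -1.63. Of these, 30.6%, 27.3%, 95.7% and 82.1% passed 2-fold, against 0.0% of unchanged genes. The criterion of this test was revised 3 times because its earlier versions, which were not met, did not allow for the shrinkage by the offset and for the simulated noise. The final version compares each estimate with the signals drawn for each array, and no analysis setting was altered. A simulated list raised 1.5-fold had a median of 0.47 and percentile 100, and 1 of 200 unchanged lists fell outside the percentile limits. The simulation was quieter than the real arrays, whose log2 ratios had an SD of 0.38 over genes and 0.29 between probes of a gene. Its noise was also drawn separately for each probe. The 0.0% of unchanged genes past 2-fold and the count of unchanged lists therefore do not give error rates for the real arrays.

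Alternatives were no background correction, median scaling, cyclic loess, an offset of 50, the authors' processed values, a detection limit of 0.05, detection on both arrays or no filter, thresholds of 1.5-fold and 3-fold, and the mean of a gene's detected probes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the lists and plots.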

Results

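The series measured messenger RNA in bone marrow from the femora of 8-day-old mice, and its title concerns blood formation in mice that lack Dnmt2. Dnmt2, whose gene symbol is Trdmt1, is an RNA methyltransferase that modifies cytosine in a small set of transfer RNAs. The labels give 1 array of wild type marrow and 1 array of Dnmt2-/- marrow, both Illumina MouseWG-6 v2.0 bead arrays, and they do not say how many animals each RNA came from. Each array held 45281 probes. At a detection p-value below 0.01, 18744 probes (41.4%) were detected on the array labelled wild type and 19580 (43.2%) on the array labelled Dnmt2-/-. The median signal was 95.1 and 100.2 intensity units, so the median probe lay close to background. With 1 array per genotype there was no replicate, no test and no error for any difference. Differences were therefore described by size, as the log2 ratio of the array labelled Dnmt2-/- over the array labelled wild type, and they describe these 2 arrays rather than the genotypes. The number of arrays limits the precision of every value.

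Dnmt2 itself was not clearly lower on the array labelled Dnmt2-/-. Its brightest probe gave a signal of 112.4 on the array labelled wild type and 148.8 on the array labelled Dnmt2-/-, a log2 ratio of 0.62 (1.53-fold higher). Another probe detected on both arrays gave -0.27. The remaining 2 probes were not detected on the array labelled wild type and were at least 1.53-fold and at least 1.58-fold higher on the array labelled Dnmt2-/-. On the array labelled Dnmt2-/- the brightest probe lay well above the fitted background of 94.9 (SD 3.43), and the other probes had signals of 107.6 to 118.2. On the array labelled wild type all 4 had signals of 84.1 to 112.4, with a fitted background of 90.9. The log2 ratio of the brightest probe was 0.22 without background correction. The position of these probes relative to the deleted part of the gene is not given in the sources used here, and a probe outside that part checks nothing. The transcript thus did not settle the genotype labels, and the arrays are named by their labels throughout.

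The arrays differed in sex-linked transcripts. Xist, the RNA that silences an X chromosome in female cells, had a signal of 822.7 on the array labelled wild type and 92.8 on the array labelled Dnmt2-/-, where it was not detected, a difference of at least 38.3-fold. Y-linked Eif2s3y, a translation initiation factor gene, had a signal of 89.8 on the array labelled wild type, where it was not detected, and 466.8 on the array labelled Dnmt2-/-, a difference of at least 16.7-fold. Y-linked Kdm5d, a histone demethylase, was at least 1.71-fold higher on the array labelled Dnmt2-/- and not detected on the other. Uty, also on the Y chromosome, was near background on both arrays, with a log2 ratio of 0.02. Over 5 settings of scaling and background correction the bound ran from 7.86-fold to 40.0-fold for Xist, 3.93 to 17.9 for Eif2s3y and 1.14 to 1.8 for Kdm5d, always in the same direction. Every comparison described here therefore sets an array with Xist signal against an array with Eif2s3y signal as well as one genotype label against the other.

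Apart from these genes the arrays were alike for most of the transcriptome. Among 9746 genes detected on both arrays, 98.4% lay within 2-fold, and the correlation of their normalized intensities was 0.983 (Pearson) and 0.977 (Spearman) across genes, which are not independent replicates. The median log2 ratio was -0.02, with 5th and 95th percentiles of -0.59 and 0.65. A further 624 genes were detected on the array labelled wild type only and 985 on the array labelled Dnmt2-/- only. At least 2-fold differences were found for 105 genes higher and 53 genes lower on the array labelled Dnmt2-/-, so that 66.5% were higher. This split depended on the scaling. It was 250 higher and 18 lower (93.3% higher) with median scaling, 22 and 3 (88.0%) without background correction, 42 and 12 (77.8%) with a larger offset, and 24 and 5 (82.8%) in the authors' processed values. With cyclic loess it was nearly unchanged, at 106 and 49 (68.4%). Different probes of the same gene gave log2 ratios with an SD of 0.29 over 3375 genes, which measures agreement between probes on the same arrays and not between animals.

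The 10 highest ratios among genes detected on both arrays ran from 3.43-fold to 6.46-fold. Trib3, a pseudokinase induced by the transcription factor ATF4, was 6.46-fold higher on the array labelled Dnmt2-/- (log2 2.69). Chac1, a glutathione-degrading enzyme also induced by ATF4, was 3.47-fold higher. Genes known from muscle were Myl3 (4.64-fold), Tnnc1 (4.19-fold), Ckmt2 (3.86-fold), myoglobin Mb (3.86-fold) and sarcolipin Sln (at least 6.58-fold), of which Mb alone was in the fixed muscle list. Col2a1, the main collagen of cartilage, was 3.90-fold higher, with log2 ratios of 1.96 to 2.29 over its 3 probes, and Comp, a cartilage matrix protein, was 3.43-fold higher, with a log2 ratio of 1.78 in that probe and 0.69 in another. Erfe, the erythroblast hormone that lowers hepcidin, was 4.29-fold higher, and Clk1, a kinase of splicing factors, 3.45-fold higher. Erdr1 was detected on the array labelled Dnmt2-/- only and was at least 11.4-fold higher there. Most of these sizes depended on the processing. Over 6 such settings, among them the authors' processed values, the difference ran from 4.22-fold to 7.37-fold for Trib3, 1.84 to 4.1 for Chac1, 1.81 to 5.2 for Myl3, 1.88 to 4.84 for Tnnc1, 1.63 to 4.31 for Ckmt2, 2.0 to 4.52 for Mb, 2.01 to 4.03 for Comp, 2.03 to 4.99 for Erfe and 2.11 to 4.09 for Clk1. The bound ran from 2.06 to 7.28 for Sln and from 2.94 to 12.2 for Erdr1. Col2a1 moved less, from 3.23 to 4.28, and 5 of the 10 highest (Trib3, Erfe, Col2a1, Clk1 and Comp) were at least 2-fold higher in each setting, while Mb fell just short in 1.

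Among the 10 lowest ratios, the chemokine Cxcl9 was 3.23-fold lower on the array labelled Dnmt2-/-, Ifi27l2a was 3.18-fold lower, and Oas1g, which senses double-stranded RNA and belongs to the interferon-stimulated list, was 2.51-fold lower. The others with a probe detected on both arrays were U2af1l4 (3.0-fold lower), the lectin Cd209f (2.91-fold), the oxysterol receptor Nr1h3 (2.66-fold), Ldhc (2.61-fold, log2 -1.38, with -0.59 in another probe) and the theta globin Hbq1a (2.52-fold). Cdk5rap1 was 3.33-fold lower, with log2 ratios of -1.74 and -1.25 in 2 probes and 0.30 in a dimmer one. Elf2 was 2.63-fold lower by its brightest probe, while its other probes detected on both arrays lay between -0.38 and 0.04. Gata4 was at least 2.49-fold and Tmem106a at least 2.36-fold lower, both detected on the array labelled wild type only and both near background. Over the same 6 settings, 2 of the 10 lowest, Ifi27l2a (2.59-fold to 3.18-fold) and Cd209f (2.12 to 2.91), were at least 2-fold lower in each. The difference ran from 1.55 to 3.3 for Cxcl9, 1.59 to 3.03 for U2af1l4, 1.97 to 3.33 for Cdk5rap1, 1.4 to 2.67 for Elf2, 1.66 to 2.61 for Ldhc, 1.64 to 2.52 for Hbq1a, 1.69 to 2.51 for Oas1g and 1.8 to 2.66 for Nr1h3, and the bound from 1.28 to 2.49 for Gata4 and 1.26 to 2.36 for Tmem106a.

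**Figure D1:**
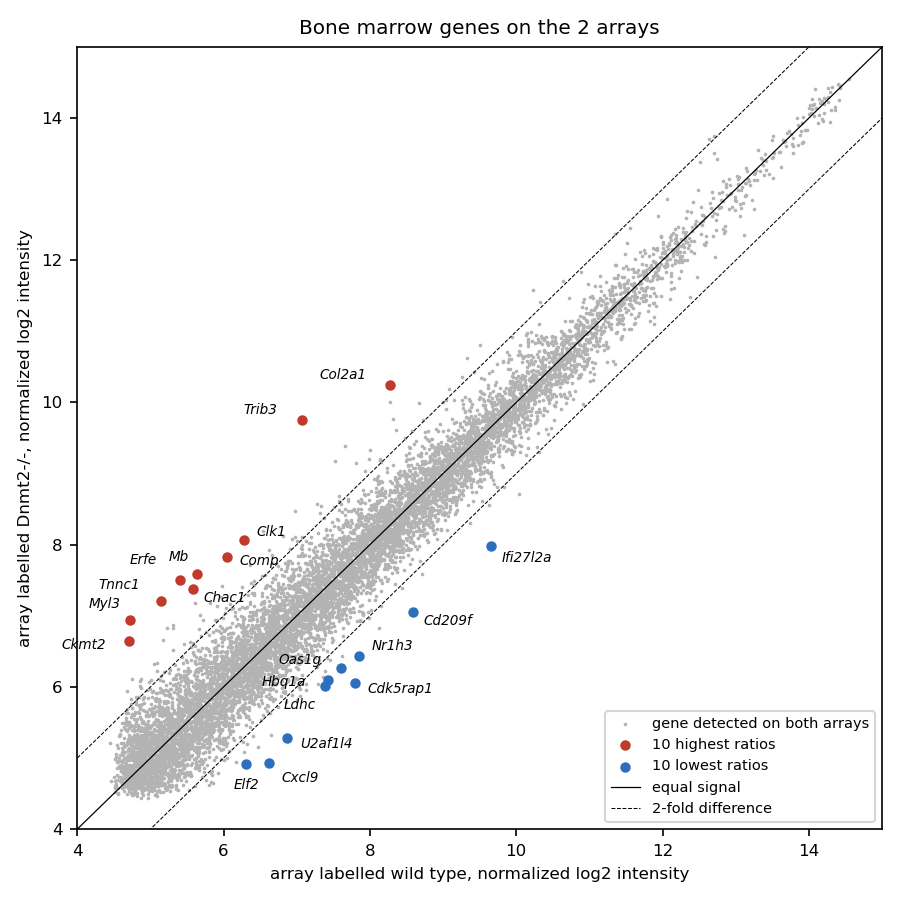
Normalized log2 intensity of each gene detected on both arrays, with the array labelled wild type on the horizontal axis and the array labelled Dnmt2-/- on the vertical axis. Each point is 1 gene, the solid line marks equal signal, the dashed lines mark a 2-fold difference, and 98.4% of the 9746 genes lie between the dashed lines. The 10 highest ratios (red) run up to a log2 ratio of 2.69 for Trib3 and the 10 lowest (blue) down to -1.74 for Cdk5rap1.

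Genes of the growing skeleton formed the highest of the gene lists fixed before the data were examined. For each list the median log2 ratio of its detected genes was set against 10000 random lists matched on mean expression, and a list is said here to stand apart when its percentile was below 0.5 or within 0.5 of the top. Of 37 lists with a median, 10 stood apart, 5 higher and 5 lower on the array labelled Dnmt2-/-. The cartilage list had a median of 0.75 (1.68-fold), with 19 of 22 detected genes higher and 14 of them by at least 1.5-fold. After Col2a1 and Comp, its highest members were Snorc (3.30-fold) and Col10a1, the collagen of hypertrophic growth plate cartilage (2.81-fold). The osteoblast and bone matrix list had a median of 0.58, with 22 of 24 genes higher, led by bone sialoprotein Ibsp (2.55-fold), Panx3 (2.38-fold), the type I collagen chain Col1a2 (2.12-fold) and the collagenase Mmp13 (2.10-fold). Bglap and Bglap2, which encode osteocalcin, did not share this, at log2 -0.05 and -0.14. The osteoclast list had a median of 0.53, with 16 of 17 genes higher, among them the fusion protein gene Dcstamp (2.21-fold), the collagen-degrading protease Ctsk (2.07-fold), Oscar (2.05-fold) and Slc9b2 (2.03-fold). Dcstamp ran from 1.39-fold to 2.6-fold over the 6 settings.

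Genes of skeletal muscle, a tissue outside the marrow, were higher on the same array. The muscle list had a median of 0.34, with 22 of 28 detected genes higher, 11 of them by at least 1.5-fold and none lower by that much. Mb, the sarcomere protein gene Tcap (2.72-fold) and the myosin light chain genes Mylpf (2.09-fold) and Myl1 (2.02-fold) led it. Mb, Mylpf, Myl1 and Tcap each varied between probes, for example from log2 0.76 to 1.95 for Mb, and Tcap ran from 1.69-fold to 3.25-fold over the 6 settings. The endothelial, stroma and adipocyte lists did not stand apart. The endothelial list had a median of 0.15 (21 of 27 genes higher), the marrow stroma and niche list 0.10 (18 of 35 higher) and the adipocyte list -0.05 (5 of 11 higher). Over 9 alternative settings the median ran from 0.28 to 0.93 for cartilage, 0.38 to 0.66 for bone, 0.35 to 0.72 for osteoclasts, 0.16 to 0.54 for muscle, 0.11 to 0.30 for endothelium and 0.05 to 0.27 for stroma.

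**Figure D2:**
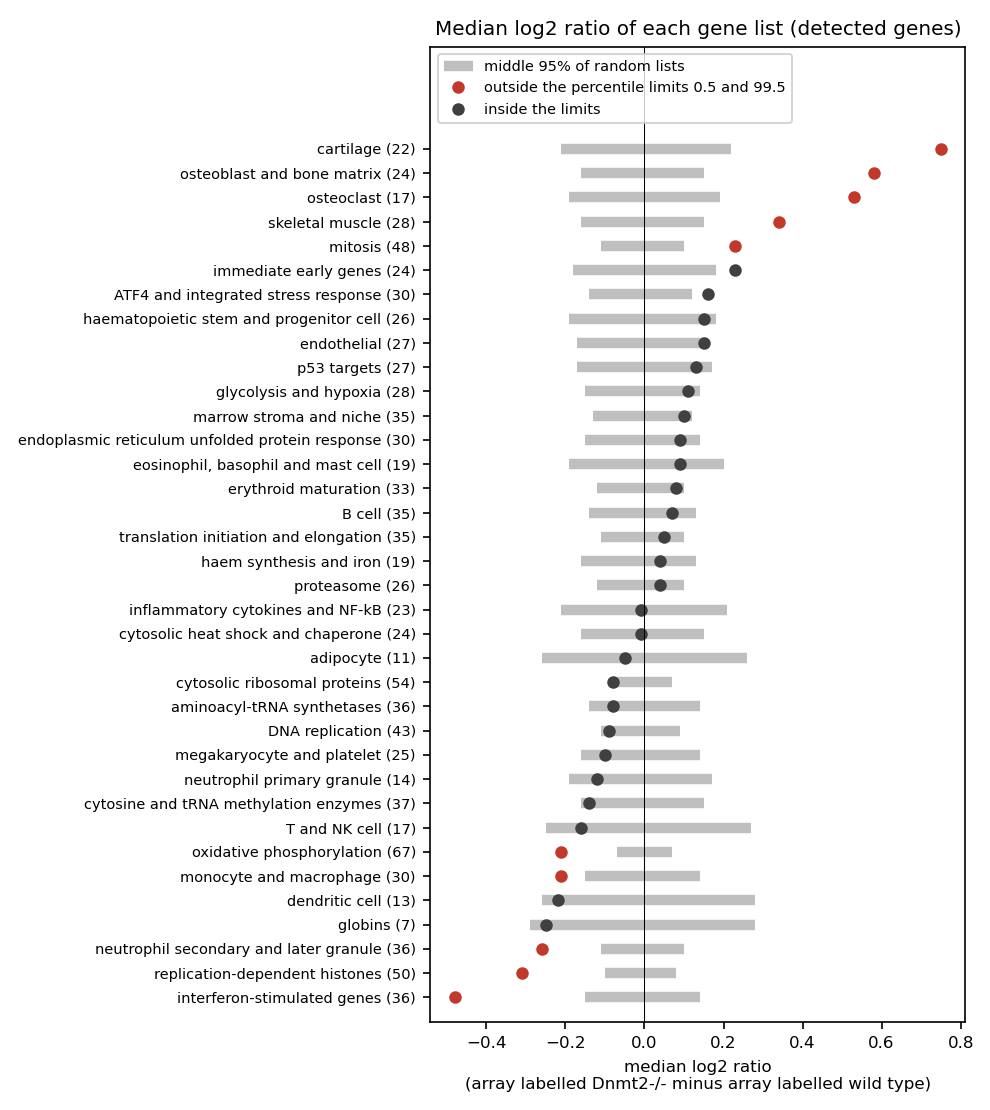
Median log2 ratio of each gene list with a median, apart from the neighbours of Dnmt2, on the horizontal axis, with the list and its number of detected genes on the vertical axis. Grey bars span the middle 95% of 10000 random lists matched on mean expression, red points are lists within 0.5 percentile points of either end, and dark points are the rest. The cartilage list lies highest at 0.75 and the interferon-stimulated list lowest at -0.48.

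Red cell genes as a group did not stand apart. The erythroid maturation list had a median of 0.08, with 19 of 33 genes higher on the array labelled Dnmt2-/-. Its highest members were the transferrin receptor Tfrc (1.84-fold), Rhag (1.67-fold), the erythroid transcription factor Klf1 (1.52-fold) and Ank1 (1.46-fold, with a log2 ratio near 0 in another probe). Genes of haem synthesis and iron handling had a median of 0.04 (10 of 19 higher), from Uros (1.39-fold), Slc25a38 (1.32-fold), Ppox (1.23-fold) and the mitochondrial iron importer Slc25a37 (1.19-fold) to the haem-degrading enzyme Hmox1, which was 1.72-fold lower. The globin list had a median of -0.25 over 7 genes (-0.26 to -0.06 over 9 alternative settings) and did not stand apart. Within it the main adult chains were close to equal, with Hba-a1 at log2 0.08 and Hbb-bs at 0.12, each on either side of 0 depending on the scaling, whereas Hbq1a (log2 -1.33), Hbb-b2 (-0.41) and Hbb-y (at least 1.67-fold) were lower. Hbb-bh1 was at -0.25 in its brightest probe and 0.07 in another. Megakaryocyte and platelet genes had a median of -0.10 (16 of 25 lower). Gng11 (1.69-fold), Clec1b (1.51-fold), Selp (1.49-fold) and Itgb3 (1.43-fold) were the lowest, and Thbs1 was 1.52-fold higher. Itgb3 was near background, with signals of 107.8 and 104.5. Over the 6 settings Gng11 ran from 1.31-fold to 1.69-fold lower, Clec1b from 1.28 to 1.51, Selp from 1.18 to 1.49 and Itgb3 from 1.09 to 1.44. Thbs1 ran from 1.17 to 1.79 higher.

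Genes of maturing neutrophils and of macrophages were lower on the array labelled Dnmt2-/-. The list of secondary and later neutrophil granule genes had a median of -0.26, with 28 of 36 genes lower. Orm1 (1.80-fold), the bactericidal protein gene Pglyrp1 (1.72-fold, although its second probe gave log2 0.14), Stfa3 (1.71-fold) and the receptor gene Csf3r (1.70-fold) were the lowest. Against the list, the gelatinase Mmp9 was 1.74-fold higher and Arg2 at least 1.5-fold higher, and Mmp9 is also a gene of the osteoclast list, whose median was 0.53. The abundant neutrophil transcripts S100a8 and S100a9 were near equal at log2 0.13 and 0.08, with S100a9 on either side of 0 depending on the scaling. Primary granule genes, which are made earlier in neutrophil development, had a median of -0.12 and did not stand apart, although 13 of 14 were lower. Nkg7 (1.89-fold), Rab44 (1.73-fold), Mgst2 (1.57-fold) and Fcnb (1.46-fold) were lowest, while the abundant Mpo and Elane were at log2 -0.06 and -0.12. The monocyte and macrophage list had a median of -0.21, with 22 of 30 genes lower, led by the scavenger receptor Cd163 (at least 1.90-fold), Adgre1, which encodes the macrophage marker F4/80 (1.86-fold), the complement gene C1qc (1.79-fold) and Clec4n (1.75-fold). Hpgd was 1.80-fold higher. Over the 6 settings the bound ran from 1.17-fold to 1.9-fold for Cd163 and from 1.1 to 1.56 for Arg2. Stfa3, with signals of 122.5 and 111.4, ran from 1.18 to 1.72 lower. With median scaling the macrophage median was -0.06 and no longer stood apart.

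Eosinophil, basophil and mast cell genes went both ways, with a median of 0.09 (10 of 19 higher). The receptor gene Il5ra (at least 1.68-fold), the mast cell protease Mcpt4 (1.71-fold), Kit (1.46-fold) and Cpa3 (1.31-fold) were higher. Il5ra and Mcpt4 were near background and ran from 1.13 to 1.77 and from 1.17 to 1.91 over the 6 settings. Alox15 (2.25-fold) was lower, as were the eosinophil granule genes Prg3 (1.92-fold), Ear10 (1.71-fold), Ear6 (1.7-fold), Epx (1.63-fold) and Prg2 (1.14-fold). In the B cell list (median 0.07, 21 of 35 higher), Myb (1.77-fold), Ms4a1, which encodes CD20 (1.73-fold), Mme (1.63-fold) and the interleukin 7 receptor gene Il7r (1.73-fold) were the highest. The second Il7r probe gave log2 -0.61. Ly6d (1.74-fold) and Pou2f2 (1.65-fold) were lower. The T and NK cell list had a median of -0.16 (11 of 17 lower), with the T cell receptor complex genes Cd3g (2.5-fold) and Cd3d (1.89-fold), the chemokine Ccl5 (2.06-fold) and Nkg7 lower and Cd247 1.81-fold higher. Dendritic cell genes had a median of -0.22 (10 of 13 lower), led by Bst2 (1.89-fold), Zbtb46 (1.82-fold), Ly6d (1.74-fold) and Siglech (1.55-fold). Stem and progenitor genes had a median of 0.15 (16 of 26 higher). Myb, Zfp521 (1.5-fold), Cd48 (at least 1.48-fold) and Kit were the highest, and Eng (1.58-fold) and Hoxb4 (1.55-fold) were lower. Cd48 was near background, with signals of 95.2 and 112.4, and its bound ran from 1.09 to 1.54 over the 6 settings. Zfp521 ran from 1.2 to 1.79 higher and Hoxb4, with signals of 124.5 and 117.3, from 1.15 to 1.55 lower. None of these 5 lists stood apart, and over 9 alternative settings the median ran from 0.04 to 0.26 for B cells, -0.41 to -0.02 for T and NK cells and 0.07 to 0.32 for stem and progenitor genes. Over the 6 settings Cd3g ran from 1.42-fold to 2.53-fold and Ccl5 from 1.31 to 2.07 lower, and Cd247 from 1.19 to 2.0 higher.

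Interferon-stimulated genes formed the lowest list. Its median was -0.48 (1.40-fold lower on the array labelled Dnmt2-/-), with 31 of 36 detected genes lower, 13 of them by at least 1.5-fold and none higher by that much. Over 9 alternative settings the median ran from -0.48 to -0.22. Oas1g (2.51-fold), the ubiquitin-like modifier Isg15 (2.0-fold), Bst2 (1.89-fold) and the antiviral protein gene Rsad2 (1.85-fold) were among the lowest, and Rsad2 and Isg15 were bright, with signals of 5433.3 and 1290.4 on the array labelled wild type. The list was lower on the array that carried the higher cartilage, bone and muscle medians and the Eif2s3y signal. Inflammatory cytokine and NF-kB genes did not stand apart, with a median of -0.01 (11 of 23 higher).

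**Figure D3:**
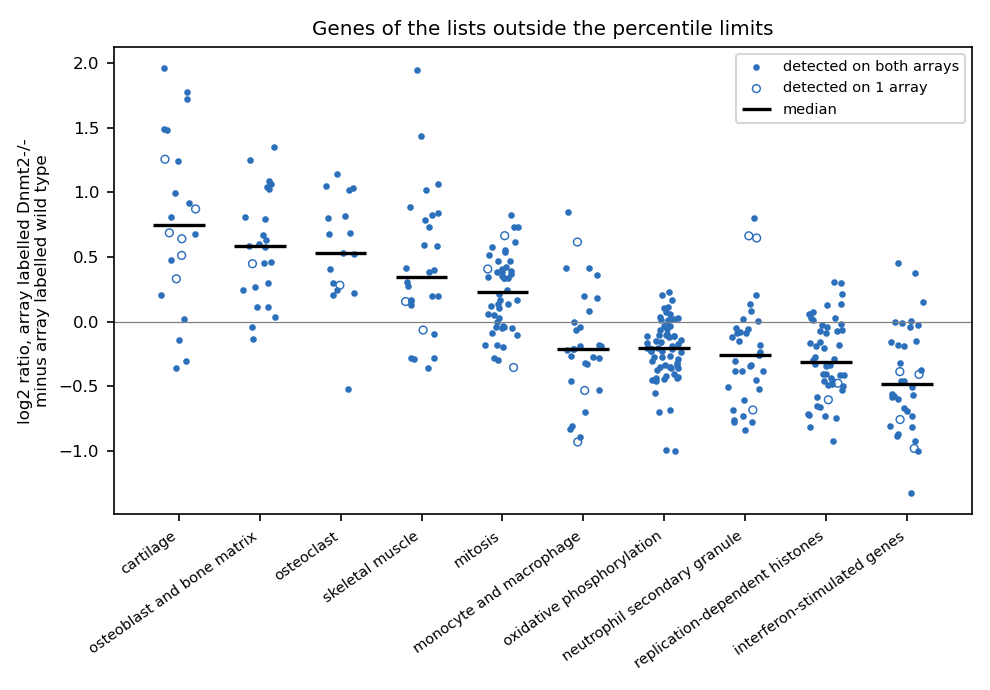
Log2 ratio of every detected gene in the 10 lists that stood apart, with the list on the horizontal axis and the log2 ratio (array labelled Dnmt2-/- minus array labelled wild type) on the vertical axis. Each point is 1 gene, filled when detected on both arrays and open when detected on 1, the black line is the list's median, and horizontal scatter is random. The medians run from 0.75 for cartilage to -0.48 for interferon-stimulated genes, and every list holds members on both sides of 0.

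By its median the mitosis list was higher, and the histone and respiratory chain lists were lower, on the array labelled Dnmt2-/-. The mitosis list had a median of 0.23, with 35 of 48 genes higher on the array labelled Dnmt2-/-, led by the cytokinesis gene Anln (1.78-fold), the kinetochore gene Spc25 (1.67-fold), Ckap2 (1.66-fold) and Ect2 (at least 1.59-fold). Only 5 mitosis genes were higher by at least 1.5-fold, and 15.71% of random lists held as many. DNA replication genes had a median of -0.09 (27 of 43 lower) and did not stand apart. Replication-dependent histone genes, whose transcripts lack the usual poly(A) tail, had a median of -0.31 (-0.31 to -0.20 over 9 alternative settings), with 40 of 50 lower, among them H4c3 (1.90-fold), H4c8 (1.76-fold), H3c3 (1.68-fold) and H4c12 (1.66-fold). Before the data were examined the histone list was fixed, with the immediate early genes, as one of sample handling. The cause of its lower median was not tested. The genes of oxidative phosphorylation had a median of -0.21 (54 of 67 lower and 13 higher), and the lowest were the small ATP synthase subunits Atp5e (2.0-fold) and Atp5k (1.99-fold) and the complex I subunits Ndufb7 (1.63-fold) and Ndufa3 (1.6-fold). Only 4 of the list were lower by at least 1.5-fold, and 13.26% of random lists held as many. These differences lay beside the higher skeletal and muscle lists on the same array.

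Lists related to the known function of Dnmt2 did not stand apart. Cytosine and tRNA methylation enzymes had a median of -0.14 (23 of 37 lower), aminoacyl-tRNA synthetases -0.08 (24 of 36 lower), translation initiation and elongation factors 0.05 (21 of 35 higher) and cytosolic ribosomal proteins -0.08 (35 of 54 lower). The ATF4 and integrated stress response list, to which Trib3 and Chac1 belong, had a median of 0.16 at percentile 99.26, inside the limits, with 18 of 30 genes higher. Medians of the remaining lists were 0.09 for the unfolded protein response of the endoplasmic reticulum, -0.01 for cytosolic chaperones, 0.04 for the proteasome, 0.13 for p53 targets, 0.11 for glycolysis and hypoxia genes and 0.23 (percentile 99.32) for immediate early genes, and none stood apart.

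The genes that flank Dnmt2 on chromosome 2 were examined one by one, since a targeted locus often keeps neighbouring sequence of the donor strain. Of 21 listed genes with a probe, 16 lay within 12 protein-coding genes of Dnmt2 in the GRCm38.p6 annotation and 8 of these were detected. The other 5 lay 45 or more genes away and were listed in error as close neighbours. Vim, the intermediate filament gene next to Dnmt2, was 1.61-fold higher on the array labelled Dnmt2-/-, and it is also a gene of the marrow stroma list. Stam was at least 1.44-fold lower by its bound, which equals its measured ratio, but its signals of 104.1 and 100.7 were near background. Over the 6 settings that bound ran from 1.09 to 1.45. Pter was at log2 0.28, Itga8 at 0.08, Rsu1 at -0.01, Mrc1 at -0.06, Hacd1 at -0.23 and Cacnb2 at -0.28, all smaller in size than the 0.29 SD between probes of a gene, and Rsu1 and Mrc1 changed sign with the scaling. Rpp38, 52 genes away, was 1.88-fold higher. The list's median was -0.01 over 9 detected genes.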

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

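Probes without a gene name in the annotation used here took no part in the comparisons. Among them, probe ILMN_2688507 had a signal of 405.6 on the array labelled Dnmt2-/- and 95.2 on the array labelled wild type, where it was not detected, a difference of at least 14-fold (3.43 to 15 over 6 scalings and value tables). Probe ILMN_1227179 was likewise detected on the array labelled Dnmt2-/- only (142.3 against 94.4), at least 2.71-fold higher (1.32 to 2.93). Both stood out because they carry signal outside the named genes on 1 array and none above background on the other. In all, 2601 unnamed probes were detected on both arrays, 17 of them at least 2-fold higher and 10 at least 2-fold lower on the array labelled Dnmt2-/-, while 567 were detected on that array only and 438 on the array labelled wild type only.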

How the results depend on the processing

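The alternatives were fixed before the data were examined, except those that set genes detected on 1 array to their bound or counted members past 1.5-fold, which were chosen after seeing the data. No paired analysis was possible because each group holds 1 array and no result comes from a test. No gene past 2-fold that the text names by the fixed rule changed sign. The 10 lists that stood apart kept the sign of their median in all 9 alternatives, and all but the macrophage list stood apart in each. With median scaling the macrophage median was -0.06 (percentile 0.81). That scaling put the median of all detected genes at 0.14, so relative to it the macrophage list was still lower. Of the lists that did not stand apart, 9 had medians that changed sign in at least 1 alternative, among them inflammatory cytokines (-0.04 to 0.22), eosinophils, basophils and mast cells (-0.07 to 0.23) and dendritic cells (-0.35 to 0.03), so no direction is read from these medians.

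Signal over background limits dim genes, and 7619 of 19057 genes were detected on neither array. Counts past 2-fold depended most on the processing, since leaving out background correction or raising the offset shrinks the ratios of dim genes by construction. Against 105 higher and 53 lower, there were 22 and 3 without background correction, 250 and 18 with median scaling, 24 and 5 in the authors' values, 42 and 12 with an offset of 50, and 106 and 49 with cyclic loess. A 1.5-fold threshold gave 644 and 503, and 3-fold gave 15 and 3. With no filter on detection there were 153 higher and 81 lower, and with the mean of a gene's probes 81 higher and 33 lower. The log2 ratio of Dnmt2 was 0.22 without background correction and 0.29 in the authors' values. Lists that stood apart only in an alternative were T and NK cells (-0.41, genes detected on both arrays), dendritic cells (-0.35, mean of probes), ribosomal proteins (-0.17, median scaling), ATF4 genes (0.15 without background correction, 0.16 with an offset of 50, 0.25 with the mean of probes) and immediate early genes (0.14 without background correction, 0.16 in the authors' values, 0.18 with an offset of 50, 0.31 with the mean of probes). The cause of these was not tested. Of 591 values of named genes under other settings, 158 moved by 0.29 or more on the log2 scale, the SD between probes of a gene, and 433 did not.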

Other observations

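The count of ATF4 genes and the tests of explanations were chosen after the result was seen, except the tests on hair and skin genes not yet looked at and on genes that escape X inactivation, whose outcome was written down first.

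Part of the ATF4 list was higher, although its median did not stand apart. Of its 30 detected genes, 10 were at least 1.5-fold higher on the array labelled Dnmt2-/- and 0 were lower by that much, and 0.0% of random lists held as many. By this count, which was picked after seeing the data, other lists whose medians did not stand apart were as rare or nearly so, with 10 marrow stroma genes higher (0.0% of random lists), 6 dendritic cell genes lower (0.0%), 6 eosinophil, basophil and mast cell genes lower (0.03%) and 6 T and NK cell genes lower (0.06%). For the dendritic cell list, 4 genes were lower by that much with genes detected on 1 array at their bound. Beside Trib3 and Chac1, the higher genes of the ATF4 list included the stress transcription factor Ddit3 (log2 1.73), the cysteinyl-tRNA synthetase Cars (1.34), Vldlr (1.30), Cebpg (1.22, with 0.21 in its other probe), the mitochondrial folate enzyme Mthfd2 (0.98) and Atf4 itself (0.69). Other known targets did not share this, with Asns at 0.25, Psat1 at 0.01 and Slc7a11 at -0.18. The endoplasmic reticulum chaperone Hspa5 was lower at -0.88. Immediate early genes went both ways, with Egr1 (1.05) and Fos (1.02) higher and Jund (-0.93) and Junb (-0.58) lower.

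Marrow stroma genes went both ways. The highest on the array labelled Dnmt2-/- were Col5a2 (log2 1.37), Lum (1.30), Fn1 (1.21), Lox (1.01) and the mesenchymal receptor Pdgfra (1.15, with 0.00 in its other probe). The signalling genes Cxcl14 (-1.32) and Bmp4 (-1.25) were lower, and the niche chemokine Cxcl12 was at 0.00. Sizes in these first paragraphs depended on the processing. Over 6 scalings and value tables the log2 ratio ran from 0.88 to 2.04 for Chac1, 0.63 to 1.58 for Cars, 0.85 to 1.54 for Vldlr, 0.46 to 1.27 for Fos, 0.68 to 1.63 for Col5a2 and 0.76 to 1.40 for Pdgfra. It ran from -0.88 to -0.26 for Hspa5, -0.93 to -0.44 for Jund, -0.58 to -0.34 for Junb, -1.33 to -0.54 for Cxcl14 and -1.25 to -0.65 for Bmp4. Psat1 (0.00 to 0.16), Slc7a11 (-0.20 to -0.04) and Cxcl12 (-0.11 to 0.03, on either side of 0) stayed small.

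The authors' processed table left probes of the sex chromosomes blank. Among probes with 1 symbol and a placed gene (GRCm38.p6), 889 of 1227 on the X chromosome and 20 of 26 on the Y were blank, against 1 of 33544 on the autosomes. All 4 Xist probes and the main probes of Eif2s3y and Kdm5d were among the blanks. The reason is not given in the sources used here.

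The first pattern weighed is the higher cartilage, bone, osteoclast and muscle lists on the array labelled Dnmt2-/-. The cartilage median exceeded the endothelial median by 0.60 and the bone median did so by 0.43, while the endothelial genes had an interquartile range of 0.36. For cartilage and bone this argues, but only weakly, against a smaller haematopoietic share that raised every other cell type alike. The range is a spread over genes and not an error, and the endothelial genes Cd34, Eng, Esam, Tek and Vwf are also in blood cell lists. For muscle (0.19) that explanation stays open, and it does not bear on osteoclasts, which are of haematopoietic origin. More tissue from outside the bone also stays open. Of 21 hair follicle and skin genes not yet looked at and detected on at least 1 array, 42.9% were at least 1.5-fold higher by their measured ratios. The share was 33.3% with genes detected on 1 array at their bound. By measured ratios 3 were lower by that much. Both shares lay between the limits of under 10% and over 50% set beforehand, and the median was 0.36 at percentile 99.14. Most of the genes counted as higher were dim and entered the set by detection on the array labelled Dnmt2-/- only. That filter favours higher ratios, so the share cannot decide. Tissue from outside the bone may account for muscle and for Krt27 (at least 3.63-fold, 1.59 to 4.08 over 6 settings) and Krt71 (at least 2.92-fold, 1.36 to 3.18). Krt27 and Krt71 were both picked for their high values. Krt10, the brightest of the hair and skin genes, was 1.56-fold lower on the array labelled Dnmt2-/-. Cartilage and bone belong to the femur itself and could reflect how much of it entered each preparation. The genotype cannot be told apart from either with 1 array labelled Dnmt2-/-.

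The second is Xist on one array and Eif2s3y on the other. RNA of female animals on the array labelled wild type and of male animals on the other is consistent with 4 genes that escape X inactivation, whose median was -0.46, with Kdm6a at -0.73, Eif2s3x at -0.66, Pbdc1 at -0.26 and Ddx3x at -0.10. A second bright Kdm6a probe gave -0.92. The support from the escape genes is weak, as a second, dimmer Ddx3x probe gave 0.59 and a dim Kdm6a probe gave 0.04. With median scaling 3 of the 4 genes were lower (median -0.35). Exchanged genotype labels cannot be told apart from correct ones. Of 4 Dnmt2 probes, 3 were higher on the array labelled Dnmt2-/-, the brightest at 0.62 and 2 by at least 1.53-fold and 1.58-fold, while the other was at -0.27. Their signals were low, at most 112.4 on the array labelled wild type and 148.8 on the other, and the place of the probes relative to the deletion is unknown. Each of the 4 Xist probes was detected on the array labelled wild type alone, and Eif2s3y on the other array alone. Whichever way the labels belong, sex-linked signal and genotype label are thus confounded in every comparison.

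The third is the lower interferon-stimulated list. Dilution of all blood cells alike by skeletal tissue is argued against, but only weakly and only as the whole cause. The erythroid median lay 0.56 above the interferon median, beyond the interquartile range of 0.40 of the erythroid genes. That range is a spread over genes and not an error. Medians of the blood cell lists went both ways, from -0.26 for later neutrophil granule genes to 0.15 for stem and progenitor genes. A part played by dilution therefore stays open. Fewer macrophages stay open, because the macrophage median lay 0.27 above the interferon median but its genes went both ways, with quartiles of -0.42 and 0.06, and Adgre1 (-0.90), C1qc (-0.84) and C1qa (-0.70) were lower than the interferon median of -0.48. The sex and the genotype of the animals also stay open and cannot be told apart, since 0 of the genotype labels had both Xist and Eif2s3y signal.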
